A study of Bos taurus with 10 samples.

How the data were processed

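Full-depth skin biopsies from cattle were compared, 5 of normal hind-foot skin and 5 of digital dermatitis lesions, with groups and replicate numbers taken from the labels. Per the labels' protocols, RNA was enriched for polyadenylated molecules and fragmented before SOLiD library preparation. TopHat 1.2.0 and edgeR are named in the submitters' processing notes. The genome build, the annotation release and the handling of reads with several alignments are not given in the sources used here, so coordinates are those of the deposited files.

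The deposited files give whole-number read counts per exon, coding segment and transcript. In all 10 files the count of a transcript equals the sum of its exon counts. The authors also deposited an RPKM value for each feature, held in the attribute text, which equals the count per kb divided by 1 constant per sample. Counts differed between strands for 5 of 5 exon pairs that share a position on opposite strands and have counts, so the counting used strand. Whether a read that spans a junction is counted in each exon it touches was not tested. Exon counts per 100 reads are therefore not taken as a percentage of reads. Rows missing from a file belonged to whole unplaced scaffolds and were taken as 0; such rows held at most 284 counts in any other sample.

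Counts were summed to 25589 genes, with each distinct exon used once per gene. Genes were kept by filterByExpr, scaled by TMM and tested by group alone with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Regions and lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for sets with at least 5 tested genes. Single values per library were compared with exact permutation tests over 252 arrangements. Figures were drawn with matplotlib 3.10.9.

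The fixed test, gene lists, naming rule and alternatives were set before the data were examined. The naming rule took up to 12 rises and 12 falls among genes with a symbol, with no overlap between groups and a mean of at least 5 CPM in the higher group, plus members of each list and a set of preset readout genes. The reference table given for cattle has 0 rows with an Ensembl identifier, so nuclear genes could not be named, and the preset readouts and all lists other than the mitochondrial one were not tested. All 37 mitochondrial genes matched that table by start and end. COX1 alone met the first part of the rule with a symbol. Identifiers were chosen by the same rule without the symbol condition. Runs of neighbouring genes, their minimum of 4 genes, the 1 Mb regions and the gene classes were chosen after seeing the data, as a replacement for names.

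Replicate correlations of log2 CPM were 0.934 to 0.971 within normal skin and 0.914 to 0.968 within lesions. The lowest chi-square per degree of freedom between replicates of a group was 41.2, so no pair of files looked like 1 library deposited more than once. Near-identical copies were defined as genes of the same transcript length whose counts lay within a factor of 1.25 in every sample, with a mean of at least 50 counts; 217 genes met this.

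The test was checked on simulated counts for the comparison of lesions with normal skin, over 14045 genes. Of simulated 2-fold changes 24 of 98 were called, and of 4-fold changes 88 of 94, with 5 unchanged genes called. Far fewer genes were changed in the simulation than were called in the data, which makes its adjusted threshold stricter. The share of 2-fold changes missed in the data is therefore not measured, and changes near 2-fold may still be missed. Alternatives covered DESeq2 1.42.0, limma-voom, other scalings, filters, collapses to genes, RPKM with pseudocounts of 1 and 0.1, a replicate block and each sample left out.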

Results

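Digital dermatitis is an infectious inflammatory disease of the skin of the bovine foot. Polyadenylated RNA from 10 full-depth skin biopsies of cattle was sequenced on the SOLiD platform. Of these biopsies, 5 were normal skin of the hind foot and 5 were large, raw digital dermatitis lesions. Total gene counts ranged from 14930128 to 24056332 per sample, and the read totals implied by the deposited RPKM values ranged from 18721477 to 32801089. The comparison asks which host genes differ in abundance between lesions and normal skin. No source used here says whether any biopsies came from the same animal, so p-values measure the spread between these samples.

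Lesions and normal skin separated along the first principal component of log2 normalised read counts (CPM, scaled by TMM-adjusted library size). This component held 52.9% of the variance. Normal samples lay between -68.8 and -54.3 on this component, and lesions between 17.1 and 92.4. Lesion biopsy 4 was the lesion closest to normal skin on this component, at 17.1. Lesion biopsy 5 stood apart from the others on the second component, at 74.96, which held 12.6% of the variance.

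**Figure D1:**
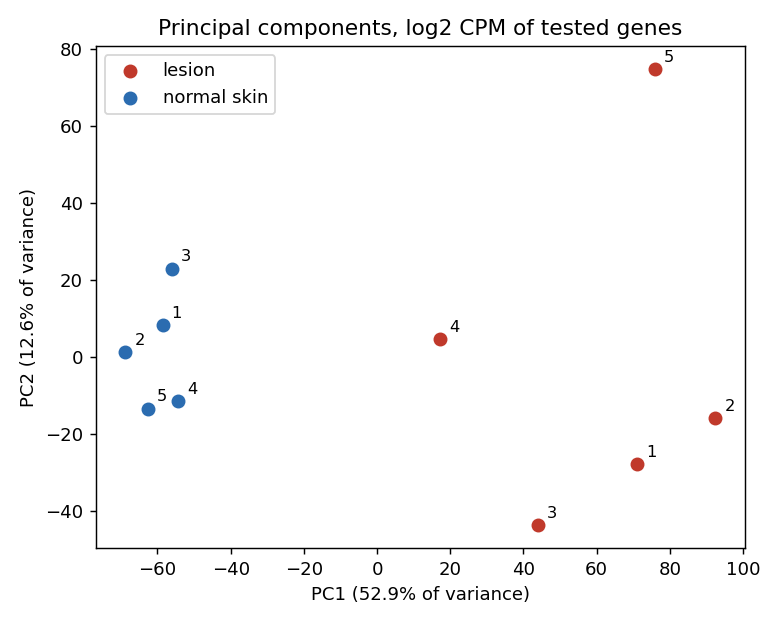
First 2 principal components of log2 CPM over the tested genes, 1 point per biopsy with its replicate number; the axes give the share of variance. The 5 normal samples sit between -68.8 and -54.3 on the first axis and the 5 lesions between 17.1 and 92.4.

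Of 14212 genes tested, 2767 differed between lesions and normal skin at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, n = 5 per group). Of these, 1336 were higher in lesions and 1431 were lower. At least a 2-fold change was found for 663 of the higher and 992 of the lower genes, and at least an 8-fold change for 92 higher and 198 lower genes. The 5 lesion values lay entirely to one side of the 5 normal values for 15.9% of tested genes, where chance gives 0.794%. The split between higher and lower genes depended on scaling: with total library size only, 418 genes were higher and 4891 lower, and the median log2 fold change of all tested genes moved from -0.03 to -0.54.

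The deposited files identify nuclear genes by Ensembl identifiers and do not pair them with names, so 2 identifiers that rose and 2 that fell are given. By fitted log2 fold change, the largest rise was that of ENSBTAG00000004097, a gene of 43 exons with 4443 coding nucleotides on chromosome 5 from 108438453 to 108487655. Its level was 1.74 ± 0.940 CPM in normal skin and 1690 ± 917 CPM in lesions (SD, n = 5 each), a log2 fold change of 9.91 (SE 0.57, edgeR adjusted p = 7.14e-06). The other was ENSBTAG00000012403, a gene of 8 exons on chromosome 9 from 71630101 to 71647095, at 0.198 ± 0.164 CPM in normal skin and 112 ± 110 CPM in lesions (log2 fold change 9.07, SE 0.90, edgeR adjusted p = 0.000282). Lesion biopsy 5 held the highest value of both genes, and without it the lesion mean of ENSBTAG00000012403 was 62.9 ± 15.8 CPM (SD, n = 4).

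The first 2 falls by fitted log2 fold change belonged to genes on the unplaced scaffold Un.004.529, each with 7 exons. Their coding lengths are alike, at 516 and 507 nucleotides, so reads may be shared between them. Whether the 2 falls are separate was not tested. ENSBTAG00000012491, from 57739 to 63019, stood at 18.9 ± 11.4 CPM in normal skin (SD, n = 5) and had 0 counts in each lesion, where normal samples held 1974 counts in all. Set against a floor of 3 counts over the lesion group, it was at least 531-fold lower (edgeR adjusted p = 0.00102). ENSBTAG00000016820, from 21995 to 26983, stood at 11.04 ± 7.67 CPM in normal skin and also had 0 counts in each lesion, at least 310-fold lower on the same floor (edgeR adjusted p = 0.000680). The floor covers counting error only. A fitted fold change against 0 counts is no measured size, so the order among the deepest falls is not settled.

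Changed genes lay side by side on the chromosomes. Runs of at least 4 consecutive tested genes called in the same direction numbered 16, and they held 92 genes. Of these runs, 9 rose and 7 fell. When the calls were shuffled over gene positions 1000 times, the mean was 2.21 runs and the highest 8. Summed CPM of the genes in each run did not overlap between lesions and normal skin, which follows in part from how the runs were chosen. The count depended on the setting. It was 8 with a stricter filter on low counts, a setting for which no shuffling was run. Other settings gave 10 without normal replicate 1, 30 with DESeq2 and 183 with total library size only. In 6 runs a member was nested within another on the same strand; with all 424 such tested genes left out, there were 14 runs (mean of 2.18 by shuffling).

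The most abundant run that rose held 8 coding genes on chromosome 5 from 30169088 to 30322279. Together they took 3.60% ± 0.882 of gene counts in normal skin and 17.8% ± 3.01 in lesions (SD, n = 5 each), and their summed CPM was 7.07-fold higher in lesions. Log2 fold changes of the members ran from 0.97 to 3.67. A run of 9 coding genes on chromosome 24, from 64405109 to 64797460, took 0.371% ± 0.116 of counts in normal skin and 3.93% ± 1.30 in lesions, with a median log2 fold change of 3.89. A run of 7 coding genes on the unplaced scaffold Un.004.290 behaved alike, at 0.462% ± 0.192 in normal skin and 4.58% ± 1.56 in lesions. Some of its members match members on chromosome 24 in length, such as ENSBTAG00000039037 and ENSBTAG00000035168, with 1669 transcript and 1173 coding nucleotides each. Whether the run on Un.004.290 is separate from that on chromosome 24 was not tested. Many members of these runs resemble each other in exon number and coding length, and how the counting divided reads between similar copies is not given in the sources used here, so the values of single members are uncertain.

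Lower down in abundance, 4 coding genes with 10 or 11 exons on chromosome 15, from 4616714 to 4792663, rose from a summed 13.4 ± 6.34 CPM to 241 ± 166 CPM (SD, n = 5 each), with member log2 fold changes from 3.00 to 7.43. Another run on chromosome 15, from 32348151 to 32352578, consisted of 1 coding gene and 3 single-exon genes without coding segments nested within it on the same strand, so its 4 calls are not separate. The remaining rising runs had median log2 fold changes between 0.60 and 1.36.

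**Figure D2:**
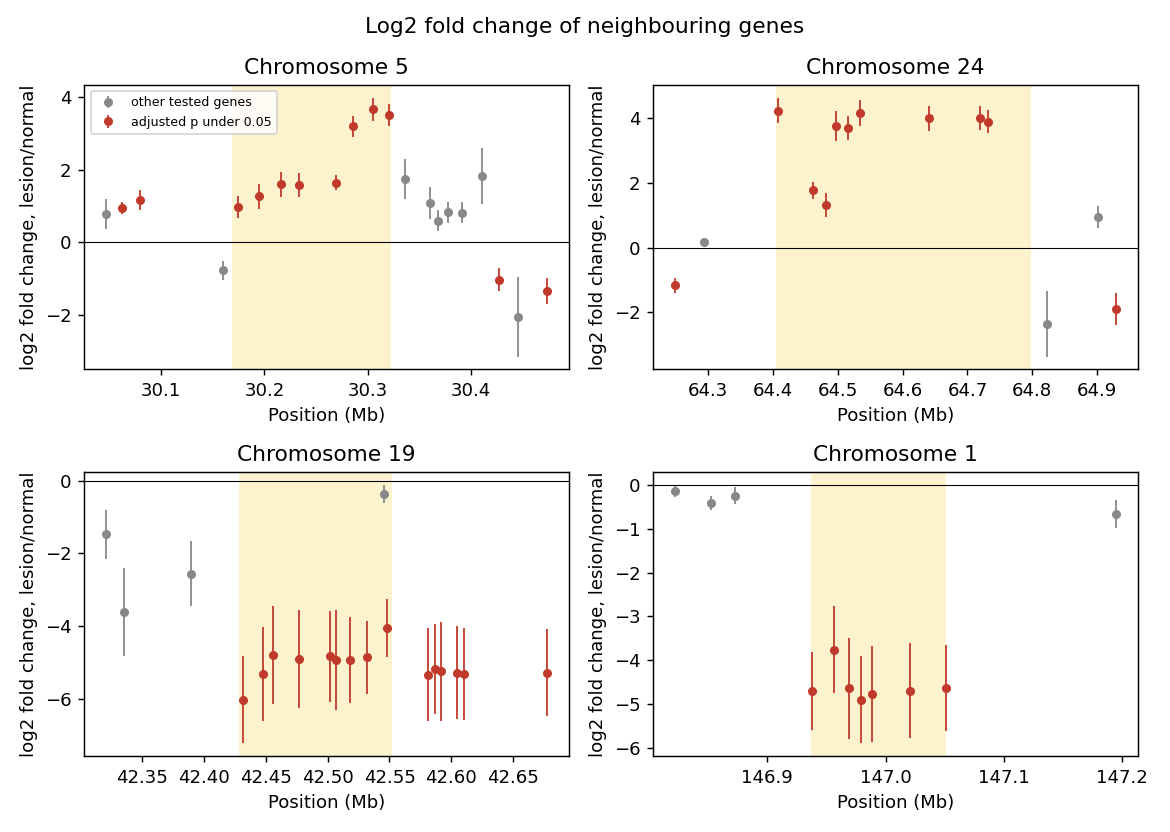
Log2 fold change, lesion over normal skin, of each tested gene by position in Mb around 4 runs; bars are standard errors, red marks an adjusted p under 0.05 and the shaded span is the run. The 8 genes on chromosome 5 reach 3.67 and the 7 genes on chromosome 1 fall as far as -4.91.

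By median log2 fold change, the deepest falls among the runs were on chromosomes 19 and 1. On chromosome 19, 9 coding genes from 42428227 to 42551962, of which 6 had a single exon, fell from a summed 1383 ± 1234 CPM in normal skin to 49.9 ± 83.3 CPM in lesions (SD, n = 5 each; median log2 fold change -4.91). A second run of 10 genes, from 42580563 to 42823921, fell from 921 ± 1058 CPM to 20.3 ± 39.2 CPM (median -5.32). On chromosome 1, 7 coding genes from 146937331 to 147051206, of which 5 had a single exon, fell from 44.95 ± 32.3 CPM to 1.81 ± 3.72 CPM (median -4.70). In all 3 of these runs lesion biopsy 4 held the highest lesion value and normal replicate 2 the highest normal value. Without lesion biopsy 4, the lesion means were 12.7 ± 3.73, 2.76 ± 0.620 and 0.149 ± 0.109 CPM, in the order given (SD, n = 4). Without normal replicate 2, the normal means of the chromosome 19 runs were 870.3 ± 527 and 482 ± 454 CPM (SD, n = 4).

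**Figure D3:**
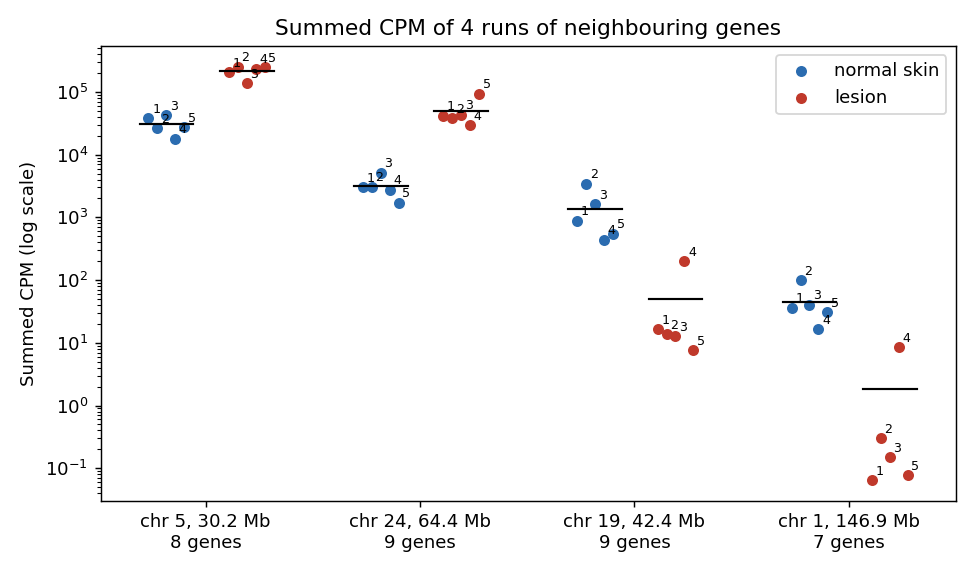
Summed CPM of the genes of 4 runs on a log axis, 1 point per biopsy with its replicate number; horizontal lines are group means. Lesion biopsy 4 lies at 199 CPM in the chromosome 19 run and at 8.47 CPM in the chromosome 1 run, above the other 4 lesions.

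The other falling runs changed less by their medians. On chromosome 23, 5 coding genes from 28483925 to 28622417 fell from a summed 3424 ± 917 CPM to 1273 ± 380 CPM (SD, n = 5 each), with log2 fold changes from -1.52 to -1.30. Runs of 4 genes on chromosomes 18, 19 and 4 had median log2 fold changes of -1.86, -1.51 and -1.54. Their lowest members were at -4.43, -3.54 and -4.98, in that order.

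A test of 1031 fixed regions of 1 Mb gave 7 past an adjusted p under 0.05, with 5 higher and 2 lower (camera, preset correlation 0.01). The number of calls cannot be told from chance: other splits of the same samples gave as many regions in 48 of 99 cases and as many as 62. Every other split mixes lesions with normal skin, and a count of regions does not judge any single region. With an estimated correlation, 0 passed (camera adjusted p = 0.998 for the first-ranked region). Of the 1031 regions, 28 had an unadjusted camera p under 0.05 there, fewer than that threshold gives by chance. The fry test called 224 regions, but it asks whether the genes of a region changed at all. It does not compare them with other genes, and 19.5% of all tested genes were changed. Of 5 gene classes tested with camera, nuclear genes without coding segments passed as higher at the preset correlation (741 genes, median log2 fold change 0.26, camera adjusted p = 0.00230). Mitochondrial tRNA genes passed as higher too (22 genes, median 0.82, camera adjusted p = 0.0104). With an estimated correlation both classes had a camera adjusted p = 0.790, and fry gave p = 0.0918 and 0.0582, in that order. Of the 741 genes, 85 were called higher and 17 lower in the gene test, where 19.5% of all tested genes were changed. Of the 22 tRNA genes 0 were called, also when adjusted over the list alone. With total library size only the median of the genes without coding segments turned to -0.25, where that of all genes was -0.54, while the tRNA genes stayed above 0 at 0.27.

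The 13 mitochondrial mRNA genes, which encode subunits of the respiratory chain and ATP synthase, were the only list fixed before the data were examined that could be tested. They had a median log2 fold change of 0.27, and the list did not pass (camera p = 0.0572, and 0.506 with an estimated correlation). With 1 sample left out, the list passed in 4 of 10 cases, without normal replicate 2, 4 or 5 or lesion replicate 3 (adjusted p = 0.0375, 0.0479, 0.0399 and 0.0141 by camera of limma, with 1 list in the family). Without normal replicate 1 its median was 0.15, and it did not pass. COX1, a subunit of cytochrome c oxidase, passed alone, at 23886 ± 2759 CPM in normal skin and 33493 ± 3340 CPM in lesions (log2 fold change 0.49, SE 0.15, edgeR adjusted p = 0.0404). Its call was lost in 14 of 25 alternative settings: in 13 its direction stayed, and in 1 it turned. Adjusted over the list alone, 0 members passed. The 2 most abundant other members were ATP6 (log2 fold change 0.28, edgeR adjusted p = 0.285) and COX3 (0.09, edgeR adjusted p = 0.742). Directions flipped with scaling: 12 of 13 members were above 0 with TMM and 12 of 13 below 0 with total library size only, where the list's median was -0.28. Relative to the median of all genes, the list's median was 0.30 with TMM and 0.26 with total library size only.

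Libraries of the groups also differed as a whole. Exon counts per 100 reads were 68.5 ± 2.90 in normal skin and 86.4 ± 2.80 in lesions (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest that 252 arrangements allow; adjusted over 8 measures, 0.0254). The 10 most abundant genes of each library took 19.6% ± 2.96 of counts in normal skin and 28.6% ± 3.81 in lesions (exact permutation p = 0.0159, adjusted 0.0254). Nuclear genes without coding segments took 5.56% ± 0.356 and 4.45% ± 0.543 (exact permutation p = 0.0159, adjusted 0.0254). This share of unscaled counts fell, while the median log2 fold change of the class was 0.26 with TMM and -0.25 with total library size only. The mitochondrial share was 12.9% ± 1.39 in normal skin and 11.1% ± 1.46 in lesions, a difference that did not pass (exact permutation p = 0.0873, adjusted 0.0998).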

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

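The tests of runs, of regions and of the runs' genes in the exon counts were chosen after the results were seen. Single libraries far from the rest of their group, by Dixon's ratio, were found in 15 of 80 groups of values. Normal, independent values would give about 4. Many of the values are CPM off the log scale, and some runs and regions share genes. The 15 are therefore no measured excess over chance.

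Lesion biopsy 4 lay far above the other lesions in the deep falling runs, at 8.47 CPM on chromosome 1 (next lesion 0.302), and at 199 CPM (next 16.5) and 90.3 CPM (next 3.32) on chromosome 19. Its mean log2 CPM over the 1 Mb region that begins at 42000001 on chromosome 19 was 4.44 (next 1.11). A wrong label is argued against: 84.9% of the genes that separate the groups without this biopsy place it on the lesion side. The same measure was lower for lesion biopsy 3, at 77.3%, and was 88.3% to 97.0% for the other lesions. A mixture with unaffected skin would move rising and falling genes alike. Lesion biopsy 4 covered a median 0.546 of the distance from normal to lesion for rising genes and 0.799 for falling genes. The difference was 0.253. Lesion biopsy 3 showed a difference of 0.278, so a mixture cannot be told apart from variation between lesions; biological differences between lesions were not tested.

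Lesion biopsy 5 held the highest value of both named rising genes, at 3275 CPM for ENSBTAG00000004097 and 308 CPM for ENSBTAG00000012403. It was also highest in the runs on chromosome 24 (93677 CPM) and Un.004.290 (110703 CPM). Mitochondrial rRNA took 6.50% of its counts, where the next lesion had 2.33%. In normal skin, replicate 1 was apart in mitochondrial rRNA (5.26%) and in mean log2 CPM over the region that begins at 32000001 on chromosome 15 (2.89). Normal replicate 2 was apart in the coding share of exon counts (70.1%), in the run on chromosome 1 that fell (100.5 CPM) and in that on chromosome 18 (199 CPM). Normal replicate 3 was apart in the run on Un.004.290 (7550 CPM).

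Exon counts per 100 reads were higher in lesions. With the genes of the runs left out of both counts and reads, the lowest lesion still lay 8.58 above the highest normal sample. Reads that span junctions may be counted more than once, which was not tested. Taking the counts of the runs from the reads could then raise the value, most where the runs take more counts. Abundant genes outside the runs, such as COX1, stayed in. A few abundant genes therefore cannot be excluded as the source. Background reads spread over the genome would raise the read density of the 11377 untested genes in normal skin. The ratio of normal to lesion was 1.07 (SE 0.139), below the 1.5 set for that explanation and below the 1.2 set against it. It lay within its SE of the bound of 1.2, a condition added after the result was seen. Under that condition background reads cannot be told apart from other sources. A biological difference in splicing or in transcript makeup was not tested.

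Runs of neighbouring genes may come from reads shared between similar copies. With 1 gene kept per group of near-identical copies there were 17 runs, but only 2 runs held such genes, so the test could not decide and shared reads cannot be told apart from joint change. Chance in the grouping of samples is argued against for the count of changed genes: 1 of 100 splits, the real one, gave as many as 2767, and the highest other gave 3. That is the smallest share that 100 splits can give. Every other split mixes lesions with normal skin, which widens the spread within its groups. For the runs the splits decide nothing: 1 of 100 splits, the real one, gave 16 and the highest other gave 0, but no other split called the 4 genes that a run needs. Chance cannot be excluded for the number of 1 Mb regions, where 49 of 100 splits, the real one included, gave 7 or more and the highest other gave 62.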

How the results depend on the processing

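The alternatives for runs and regions, and those that dropped near-identical copies, lesion biopsies 4 and 5 together, or the genes of the runs, were chosen after seeing the data. The count of 2767 changed genes stayed within 1.5 times except with total library size only (5309) and at a minimum of 2-fold (1655). The genes called varied more. Apart from the 2-fold minimum, settings kept from 58.4% (RPKM plus 0.1, 12210 genes tested) to 99.6% (DESeq2) of the 2767 in the same direction. Total library size only kept 66.8%. No setting called any of them in the opposite direction. Each sample left out in turn gave 1952 to 3064 genes. Higher genes (1336) became 418 with total library size only, 650 with RPKM plus 1, 634 with RPKM plus 0.1, and 663 at 2-fold. Lower genes (1431) became 4891 with total library size only. Higher genes were 48.3% of calls with TMM, 7.87% with total library size only, 33.7% with RPKM plus 1 and 34.3% with RPKM plus 0.1. The replicate block gave 2055 genes. Numbers did not pair samples: correlations of same-numbered samples were -0.183 to 0.0458, and 2 of 10 samples correlated best with their own number. Without lesion biopsies 4 and 5 there were 2770 genes.

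Runs (16) numbered 30 with DESeq2, 183 with total library size only, 8 with the stricter filter, 14 without nested genes, 10 to 23 with 1 sample left out, and 24 without lesion biopsies 4 and 5. A minimum of 3 genes gave 84 runs (22.4 by shuffling) and of 5 genes 8 runs (0.206 by shuffling). Regions (7) numbered 0 with an estimated correlation, 224 with fry, 11 with total library size only, and 7 to 14 with 1 sample left out. The mitochondrial list had medians from 0.15 to 0.37 with 1 sample left out, with p from 0.0141 to 0.159, and -0.28 with total library size only. COX1 lost its call in 14 of 25 settings, with adjusted p from 0.00141 to 0.843. With total library size only COX1 was -0.0452, ATP6 -0.26 and COX3 -0.43. COX3 was -0.0876 with either RPKM setting. The 4 named identifiers kept direction and call in all 25 settings. PC1 held 71.8% with the 500 most variable genes. The cause was not tested for these changes, other than fewer genes or samples where a setting removes them. Leaving out hair and hard keratins was not run, since nuclear genes have no names here. Depth limits calls of genes with few counts.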

Other observations

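Both hypotheses here come from the same data that showed the runs. The test of neighbours outside the runs was chosen after the result over all neighbours was seen.

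The first hypothesis is that neighbours built alike, as members of tandem gene families are, shift together in lesions. Over neighbouring tested coding genes, near-identical copies left out, 42 of 277 pairs with the same exon number and coding lengths within 10 percent were called in the same direction (15.2%), against 384 of 12011 other pairs (3.197%; two-sided Fisher's exact p = 4.13e-16). Of these 42 pairs, 14 hold genes of the runs that prompted the hypothesis, so that comparison cannot decide. With every pair that holds a gene of a run left out, 28 of 261 pairs built alike were called in the same direction (10.7%), against 332 of 11935 others (2.78%; two-sided Fisher's exact p = 3.33e-09). Pairs are not independent replicates, and reads shared between less similar copies would predict the same, so this is consistent with joint change of gene families without showing it.

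The second hypothesis is that the falling runs of short single-exon genes on chromosomes 1 and 19 may hold hair keratin-associated protein genes, which the reference table (ARS-UCD2.0) places on those chromosomes. If such genes fell in general, single-exon coding genes of these chromosomes would be called lower more often outside the runs too. There, 5 of 40 were called lower (12.5%), against 20 of 339 on other chromosomes (5.90%; two-sided Fisher's exact p = 0.165). The difference did not pass, and the genes of the runs remain without names.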
